A study of Caenorhabditis elegans with 3 samples.

How the data were processed

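The data were chromatin immunoprecipitation sequencing (ChIP-seq) peak lists from mixed-sex first-larval-stage (L1) Caenorhabditis elegans. The worms were of strain OP177, which carries an unc-119 mutation and the integrated transgene wgIs177, with egl-27 fused to green fluorescent protein (GFP). EGL-27 is a relative of the metastasis-associated (MTA) proteins of nucleosome remodelling and deacetylase (NuRD) complexes and has a GATA-type zinc finger. The labels number 3 biological replicates, and all of them formed a single group. Per the labels, replicates 1 and 2 came from a stock centre and have a size range of 150 to 350 bp. Replicate 3 came from the submitting laboratory and is labelled as sonicated with a microtip. No untreated or untagged sample was part of the series used here.

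Each replicate had a relaxed peak list, which keeps background as input for the irreproducible discovery rate (IDR) procedure. A relaxed list of the pooled replicates and the authors' optimal IDR-thresholded list stood beside them. Peaks were therefore called both per replicate and on the pooled replicates. Per the deposited library notes, every list was made against the same control alignment, which was not used here. The aligner, the peak caller and the IDR threshold were not given in the sources used here. The height of each peak is the signal value that the authors' caller gave it, and it was used only to rank or describe peaks within a list. The significance of each peak was deposited as a -log10 q-value, with many ties at the top of each list, so it was not used for ranking. Read depth was not given in the sources used here, so the precision of a single peak height is unknown.

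The authors supplied every list in builds ce10 and ce11. The ce11 lists were analysed with the WBcel235 genome and Ensembl annotation release 115, whose chromosome names and lengths fit ce11. The ce10 lists served only for counts per list and per chromosome, set against ce11 chromosome lengths, because a ce10 genome was not used here. Peaks were ranked by signal, ties by position, and the summit was the position named in the list. Coordinates are 1-based.

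A promoter was the span from 1000 bp upstream to 500 bp downstream of any annotated transcript 5′ end of a protein-coding gene. A gene was bound when an IDR summit lay in that window. Summits outside promoters were assigned, in this order, to coding exons, untranslated regions (UTRs), introns, non-coding genes or pseudogenes, and intergenic sequence. The non-coding class left out piRNA genes, so a summit in one was assigned by the other annotation there or as intergenic. The share in each class was compared with 10000 random placements of the summits on their own chromosomes by a permutation test. That test was one-sided for the promoter share on its own and two-sided for all 6 classes, with Benjamini-Hochberg adjustment over the classes. Fisher's exact test compared the classes with relaxed pooled peaks that overlap no IDR peak. Shares per chromosome and in the central 33.3% of the length of the autosomes were compared with sequence length by exact binomial tests, two-sided. Intervals of shares are exact 95% binomial intervals and cover counting error only.

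Replicates were compared through the 705 highest-signal peaks of each, the number of IDR peaks, so that list length did not enter. An IDR peak was recovered when its summit lay inside a top peak of the replicate, and 1000 random placements gave the chance level. Overlap between replicates needed 1 bp. Gene lists, 30 in all, were tested with Fisher's exact test, two-sided, against the other protein-coding genes, with Benjamini-Hochberg adjustment over all lists. MicroRNA genes were tested against all other annotated genes. For 14 fixed motifs, presence on either strand within 50 bp of the summit was compared with an equal window centred 300 bp to the right of the same summit by the exact McNemar test, two-sided. All 2080 merged 6-mers were searched in the same way. Genes and peaks are not independent replicates, and these p-values measure neither the spread between worms nor that between libraries. Values per replicate are given where each replicate has its own list.

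The genes named were set by a fixed rule. They were egl-27 and unc-119, the 15 IDR peaks of highest signal, the 4 bound members of highest signal in each list past an adjusted p of 0.05, and at most 2 members of every other list. For 4 lists on development and chromatin (the Wnt, Hox, NuRD and GATA lists), every bound member and up to 3 unbound ones were named. A top peak took the name of a gene with a transcript 5′ end within 2000 bp, otherwise of the gene body around it. Genes named outside this rule were chosen after their values were seen: ogt-1 for the peak 2051 bp away, and the genes beside groups of peaks or nearest to peaks at any distance. The groups, lists, motifs, tests and most alternatives were fixed before the data were examined. These alternatives changed the promoter window, the 5′ ends used, the background, the overlap rule, the number of top peaks, the motif window, the build and the threshold, and left out each replicate in turn. Shuffled windows, nearest 5′ ends at any distance and leaving out the egl-27 region were among the alternatives chosen after the data were seen. Leaving out a replicate kept only IDR peaks whose summit lay in the top lists of the other two. The IDR list itself still came from all 3 replicates. This setting therefore only shortens the list, and the number of bound genes cannot rise under it.

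The tests were checked on simulated data. A list with 6 times the odds of binding of the 19985 protein-coding genes was called in 86.0% of 50 simulations, with a median estimated odds ratio of 6.04. The lists raised in this way had 63 to 1299 members. Shorter lists, such as the Wnt, Hox, NuRD and GATA lists, were not simulated, so that rate does not apply to them. Random placement of all summits gave a promoter p under 0.05 in 7 of 100 simulations. In 1 simulation, a motif planted in 20% of the windows was recovered and no other fixed motif was called. Its summit and flank windows had the same base composition, unlike the real ones (48.2% and 35.7% GC). False calls from that difference were therefore not checked. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.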

Results

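EGL-27 occupancy was mapped by ChIP-seq against GFP in whole L1 larvae, with 3 biological replicates of the same strain and stage. The relaxed lists held 15286 peaks in replicate 1, 30000 in replicate 2 and 30000 in replicate 3, and 23218 for the pooled replicates. The authors' IDR-thresholded list held 705 peaks, with signal values from 31.5 to 252.5 and a median of 42.9. All 705 were the 705 highest-signal peaks of the pooled list, and 691 of them were 390 bp wide. The question that the labels give is where EGL-27 binds at this stage. No second condition was part of the series used here, so comparisons were made between replicates, with random placement and within the genome.

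The replicates differed in most of their strongest peaks. The top lists of replicates 1, 2 and 3 recovered 383, 403 and 528 of the 705 IDR peaks, which is 54.3%, 57.2% and 74.9%. The mean recovery was 62.1% ± 11 (SD, n = 3), while random placement recovered at most 1.28% in any of 1000 placements per replicate. Because the IDR list was drawn from the pool of these replicates, recovery above random placement follows from its selection and does not measure reproducibility. All 3 top lists held 198 of the IDR peaks (28.1%), at least 2 held 453, and none held 42. In the whole relaxed lists, the summits of 88.9%, 94.9% and 99.6% of IDR peaks lay inside a peak. Between replicates, the top lists overlapped by 40.2% for replicates 1 and 2, 47.9% for 1 and 3, and 45.6% for 2 and 3, a mean of 44.6% ± 3.93 (SD, n = 3 pairs). Replicates 1 and 2, which share their labels for stock and size range, were thus not the pair with the highest overlap. Mitochondrial peaks separated the replicates in another way. They made up 8 of the 100 strongest peaks of replicate 1 and 24 of those of replicate 2, and 0 of 30000 peaks in replicate 3. With n = 3 no test between replicates was run.

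**Figure D1:**
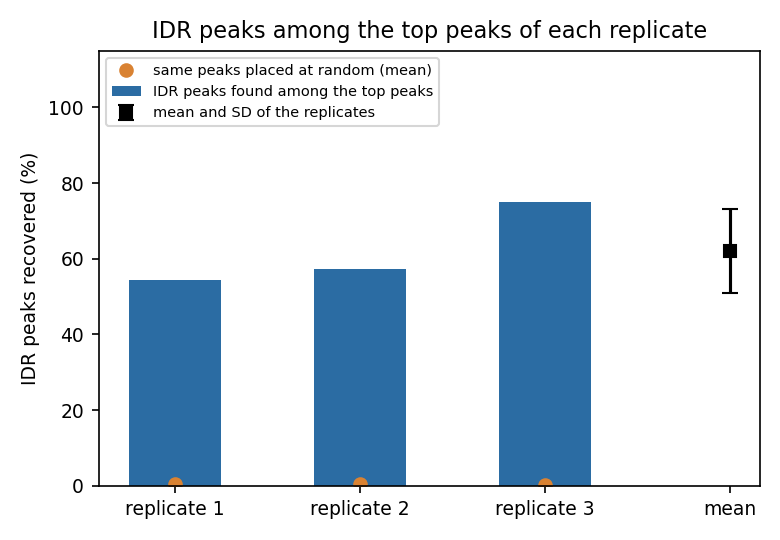
Share of the 705 IDR peaks (y axis, percent) whose summit lies in the 705 highest-signal peaks of each replicate (bars), with the mean and SD of the 3 replicates (square) and the mean of 1000 random placements (circles). Recovery was 54.3%, 57.2% and 74.9%, and random placement stayed near 0.

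The strongest EGL-27 peaks lay mostly outside coding sequence, in promoters, introns and intergenic stretches. The highest-signal peak (252.5) lay in an intron of Y111B2A.12 on chromosome III, 12612536 to 12612810. Peaks 2 and 14 (206.3 and 112.2) both lay upstream of ogt-1, which encodes O-GlcNAc transferase, at 7155775 to 7155881 and 7153836 to 7154225 on chromosome III. The second of these lay in its promoter and the other in intergenic sequence 2051 bp from its 5′ end. Peak 4 (169.3) lay in an intron of egl-27 itself, on chromosome II at 6842704 to 6843093, within the promoter window of an internal 5′ end. The RNA-binding protein genes sup-26 (148.7, intergenic, 1925 bp away) and puf-9 (139.9, promoter) followed. Further peaks lay in an intron of pqn-41 (136.9), in the promoter of the 14-3-3 gene ftt-2 (135.9) and in an intron of Y43F8B.2 (113.5). The peak near F55G7.5 (112.3) and that near the hypoxia factor gene hif-1 (112.2) were intergenic, the latter 1956 bp from a 5′ end. The remaining 3 nuclear peaks, with signals of 133.8, 132.2 and 130.6, were intergenic on chromosome X, between 3001 and 6014 bp from the nearest 5′ end. Peak 3 (184.9) was mitochondrial, near ND1, and was absent from the lists of replicates 1 and 3. Of the 15 peaks, 6 were on chromosome X.

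EGL-27 summits concentrated in promoters and avoided coding exons. Promoters held 372 of 705 summits (52.8%, 95% interval 49.0 to 56.5), compared with 31.1% at random placement, a 1.70-fold excess. Coding exons outside promoters held 3 summits (0.426%) against 16% at random, introns 16.6% against 24.9%, and UTRs 0.851% against 2.48%. Non-coding genes other than piRNA genes, with pseudogenes, held 4.54% against 3.05%. Intergenic sequence held 24.8% against 22%, which did not pass the threshold (adjusted permutation p = 0.081). The median summit lay 784 bp from the nearest protein-coding 5′ end, and 177 summits (25%) lay more than 2000 bp away. In all, 444 of 19985 protein-coding genes (2.22%) were bound, and 91 promoter summits lay in the windows of 2 or more genes. The promoter excess had a permutation p of 0.0001, the smallest that 10000 placements can give, and the depletions in coding exons and introns an adjusted permutation p of 0.0004. Relaxed peaks outside the IDR list were in promoters less often, at 38.2% (Fisher's exact test, odds ratio 1.81, p = 1.3e-14). Against these peaks the intergenic share passed, at 24.8% against 20.9% (odds ratio 1.25, adjusted p = 0.013 by Fisher's exact test). The other classes differed from them in the same direction as from random placement. Each replicate's own strongest nuclear peaks gave promoter shares of 49.4%, 51.2% and 49.6% (mean 50.1% ± 0.993, SD, n = 3). The excess in non-coding genes (adjusted permutation p = 0.038) was lost when any replicate was left out, with ratios from 1.07 to 1.27, and among the 352 peaks of highest signal (1.55-fold). The intron depletion lost its call without replicate 2 (0.780-fold) and the UTR depletion without replicate 2 (0.261-fold) and among the 352 peaks of highest signal (0.340-fold). Intergenic sequence passed without replicate 1 (1.26-fold) and without replicate 3 (1.28-fold).

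**Figure D2:**
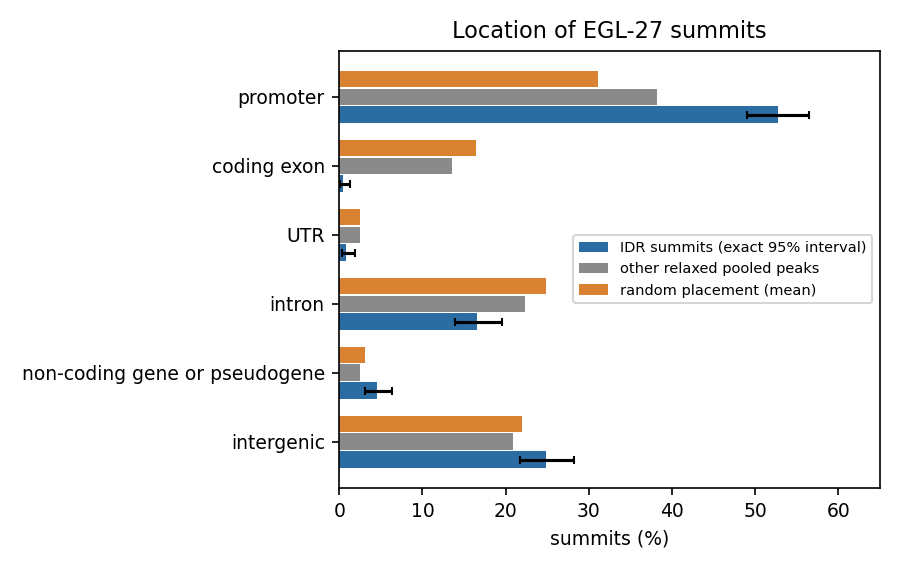
Share of summits (x axis, percent) in each annotation class for the 705 IDR summits with exact 95% intervals, for the other relaxed pooled peaks, and for random placement. Promoters held 52.8% of IDR summits and 31.1% of random placements, and coding exons 0.426% and 16%.

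Chromosome X carried more EGL-27 peaks than its length accounts for, and chromosome V fewer. X held 169 of 704 nuclear peaks (24.0%) against 17.7% of sequence, a 1.36-fold excess (exact binomial test, adjusted p = 7.5e-05). V, which is rich in chemoreceptor genes, held 87 (12.4%) against 20.9% (0.592-fold, adjusted exact p = 3.3e-08). III held 125 (17.8%) against 13.7% (1.29-fold, adjusted exact p = 0.0061). Counts on I, II and IV did not pass the threshold, with 117, 97 and 109 peaks and ratios of 1.11, 0.904 and 0.887. Before adjustment over chromosomes, II was depleted at an exact p under 0.05 against gene 5′ ends (0.798-fold), without the egl-27 region (0.814-fold), without replicate 1 (0.732-fold) and without replicate 3 (0.686-fold), and IV without replicate 3 (0.719-fold). The X excess was present for promoter summits (1.44-fold) and for summits outside promoters (1.42-fold). Each replicate's own top nuclear peaks placed 23.5%, 22.4% and 25.5% on X (mean 23.8% ± 1.58, SD, n = 3). Within the autosomes, the central part, 33.3% of the length, held 44.9% of peaks, 1.35-fold more by the exact binomial test (p = 3.2e-08). Protein-coding 5′ ends are themselves more central (38.1%), and against them the excess was 1.18-fold (exact binomial p = 0.0016). The call on chromosome III was lost without replicate 1 (1.26-fold), without replicate 2 (1.19-fold) and among the 352 peaks of highest signal (1.18-fold).

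Genes of the translation machinery were bound more often than other genes. Among cytosolic ribosomal protein genes, 21 of 81 were bound (25.9%, 95% interval 16.8 to 36.9), compared with 2.13% of other genes (odds ratio 16, Fisher's exact test, adjusted p = 1.4e-15). The 21 genes comprised 12 of the large and 9 of the small subunit, led by rpl-3 (signal 103.5), rpl-20 (91.3), rps-28 (88.2) and rps-12 (82.2). All 21 summits lay upstream of the 5′ end, at 37 to 718 bp with a median of 308 bp, and 14 of them were in the top lists of at least 2 replicates. The excess kept its call and shrank against genes with a relaxed peak (odds ratio 8.30) and with the nearest 5′ end at any distance (13 of 81 bound, 6.11). In lists matched by upstream distance it was 9.16 times the expected number, and 8 to 11 genes were bound without each replicate. Translation factor genes had 7 of 39 bound (17.9%, odds ratio 9.77, adjusted p = 0.00021 by Fisher's exact test). The highest-signal members were eef-1A.2 (98.2), iff-2 (84.1), eef-2 (41.7) and eef-1G (38.8), which encode elongation and initiation factors, and all 7 summits were upstream of the 5′ end. For translation factors the odds ratio was 5.91 against genes with a relaxed peak and 5.75 with the nearest 5′ end at any distance. Their call was lost among the 352 IDR peaks of highest signal (2 of 39 bound, odds ratio 5.03, adjusted exact p = 0.33) and without replicate 2 (2 of 39, odds ratio 6.21, adjusted p = 0.32). Genes were not matched by expression level, and no untagged sample was used here. Signal at these promoters that does not come from EGL-27 was therefore not excluded.

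Chemoreceptor genes, a large family of sensory receptors, seldom had an EGL-27 peak at their promoters. Of 1299 genes, 2 were bound (0.154% against 2.37% of other genes, odds ratio 0.0636, Fisher's exact test, adjusted p = 1.1e-09). Peaks came from whole larvae and read mappability was not examined, so absence of EGL-27 from these genes was not shown. The bound members were srh-2 (63.7) and srz-62 (35.8). Against genes with a relaxed peak the odds ratio was 0.140. When any replicate was left out 0 members were bound, but that setting keeps 239 to 305 peaks and cannot raise the count. Of 261 microRNA genes, 12 were bound (4.6% against 1.89% of other annotated genes, odds ratio 2.5, adjusted p = 0.035 by Fisher's exact test). These 12 genes shared 8 summits. The strongest lay upstream of mir-54, mir-55 and mir-56 (77.4), followed by mir-354 (54.1), whose summit also lay in the rps-20 promoter. The microRNA call was lost under most alternatives. It was absent when each summit was given only to the nearest 5′ end (odds ratio 1.10), against genes other than piRNA genes (1.83, adjusted exact p = 0.18) and without replicate 1, where the odds ratio was 0.971 with 2 genes bound.

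Among the lists closest to the known roles of EGL-27, few genes were bound and no list passed the threshold by Fisher's exact test. EGL-27 acts in Wnt-dependent cell polarity and in cell migration and patterning. Of 30 Wnt pathway genes only mig-5, a Dishevelled homologue, was bound (57.0, chromosome II at 8185006 to 8185395, adjusted exact p = 0.68), while egl-20, lin-44 and cwn-1 were not. Of 11 Hox genes and cofactors 0 were bound, which allows a share of up to 28.5% (exact 95% interval), and ceh-13, lin-39 and mab-5 were among them. NuRD and related complex genes had 2 of 14 bound, egl-27 (169.3) and lin-53 (42.6), with lin-40, let-418 and chd-3 unbound (adjusted exact p = 0.14). The NuRD list passed with 2000 bp upstream windows, with 4 bound (odds ratio 12.1, adjusted exact p = 0.0041). With the 1000 bp windows, 1 gene was bound without the egl-27 region (odds ratio 3.41), and 1 without each replicate. GATA factor genes had 1 of 11 bound, the epidermal regulator elt-1 (34.4, chromosome IV at 9615448 to 9615837), with elt-2, elt-3 and elt-4 unbound (adjusted exact p = 0.48). Seam and epidermal genes had 2 of 25 bound, vab-10 (37.7) and elt-1 (adjusted exact p = 0.29). For both the GATA and the seam list, 0 genes were bound when any replicate was left out, with only the outermost 5′ end, or among the 352 peaks of highest signal. The egl-27 peak lies in the region that the transgene carries.

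Other lists with high shares also missed the threshold by Fisher's exact test. Insulin signalling and stress genes had 4 of 40 bound (odds ratio 4.93, adjusted exact p = 0.058), led by xbp-1 (50.6) and akt-2 (42.9). Their call passed with 2000 bp upstream windows (odds ratio 5.35, adjusted exact p = 0.0070), with only the outermost 5′ end (5.47, 0.0495) and with only the nearest 5′ end (6.24, 0.040). With the 1000 bp windows, 0 of 40 were bound without replicate 1, 1 without replicate 2 (odds ratio 2.93), 0 without replicate 3, and 1 among the 352 peaks of highest signal (2.38). Heterochronic genes, which time larval development, had 2 of 12 protein-coding members bound, alg-1 (56.3) and lin-28 (43.3), with an adjusted p of 0.12. With 2000 bp upstream windows 4 of 12 were bound and the list passed (odds ratio 15.1, adjusted exact p = 0.0032), while 0 were bound with only the outermost 5′ end and 0 without replicate 2. Nuclear hormone receptors had 10 of 269 bound, led by nhr-48 (75.2) and nhr-58 (54.3), with an adjusted p of 0.285, and passed with the nearest 5′ end at any distance (22 of 269, odds ratio 2.86, adjusted exact p = 2.5e-04). With the 1000 bp windows the number bound was 5, 4 and 2 without replicates 1, 2 and 3 (odds ratios 2.19, 1.74 and 0.984), so the excess was absent without replicate 3. F-box genes had 1 of 315 bound, fbxb-85 (39.5), with an adjusted p of 0.058, and C-type lectins 1 of 237, clec-126 (39.0), with an adjusted p of 0.23. With 2000 bp upstream windows both lists passed as depleted (odds ratios 0.190 and 0.126, adjusted p 0.013 and 0.027). The bHLH and T-box list had 2 of 43, hlh-11 (95.3) and hlh-30 (32.7), and detoxification enzymes 2 of 215, cyp-13A2 (37.0) and gst-27 (32.3). A single bound gene was found for cuticle collagens (1 of 181, col-85), muscle (1 of 28, act-4), pan-neuronal genes (1 of 30, rgef-1), neuropeptides (1 of 140, ins-39) and pharynx (1 of 14, peb-1). The same held for core histones (1 of 50, his-37), ceh homeobox genes (1 of 63, ceh-38) and cell cycle genes (1 of 31, lin-35). No member was bound of 85 hedgehog-related, 29 intestine, 24 neuronal fate, 35 germline, 31 major sperm protein or 33 proteasome genes. The lists with 1 or 0 bound genes in these last sentences did not pass the threshold.

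**Figure D3:**
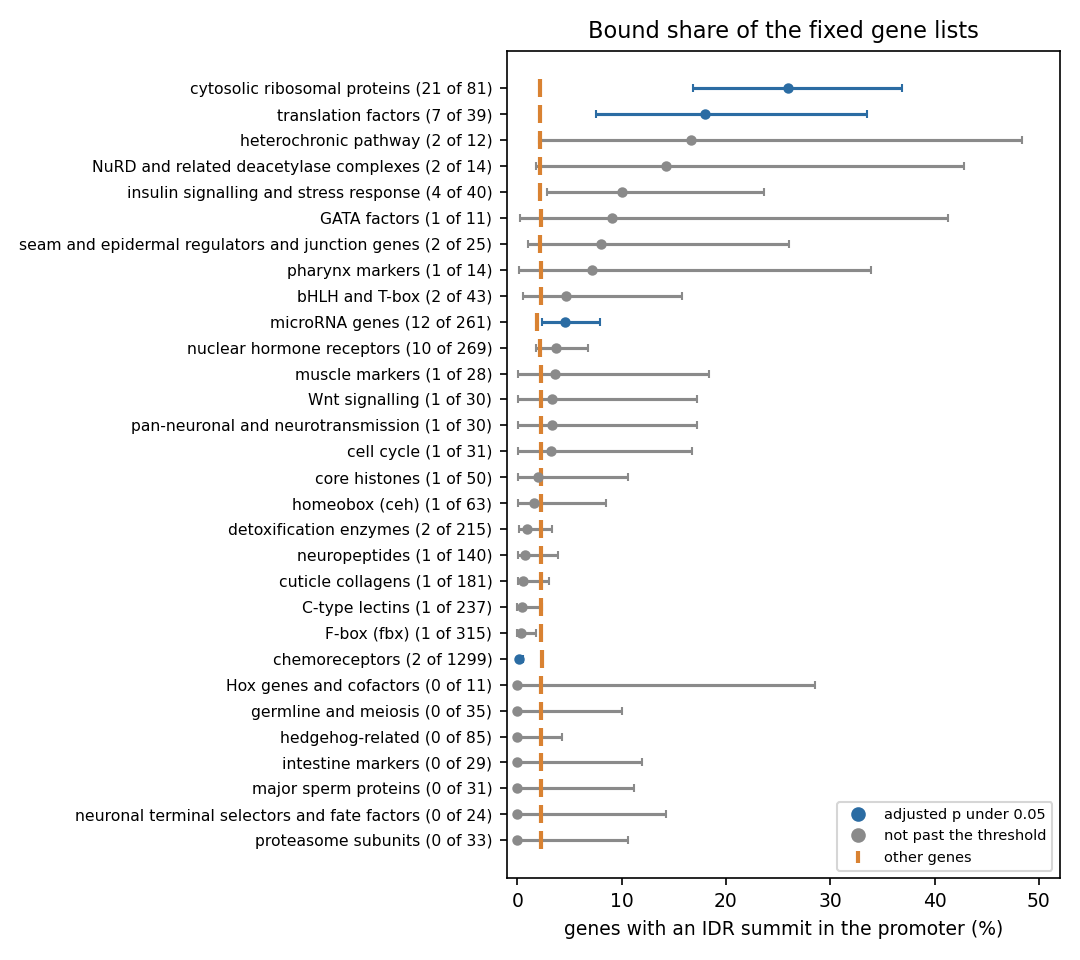
Share of genes with an IDR summit in the promoter (x axis, percent) for each of 30 fixed gene lists, with exact 95% intervals and bound counts beside the names. Vertical ticks mark the share among other genes, near 2%, and blue points mark the 4 lists past an adjusted p of 0.05, of which ribosomal proteins reach 25.9%.

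The sequence under EGL-27 summits was rich in GA repeats and in the CTGCGTCTC motif, while GATA sites were not more frequent than in flanks. GAGAGA lay within 50 bp of 291 of 704 nuclear summits (41.3%) and in 7.95% of flank windows, a 5.2-fold difference (exact McNemar test, adjusted p = 1.8e-47). CTGCGTCTC, a motif known from highly occupied regions of this genome, was at 15.2% of summits and 0.852% of flanks (17.8-fold, adjusted exact p = 7.2e-25). The E-box CACGTG was at 6.53% against 1.99% (adjusted exact p = 1.1e-04), and the general E-box CANNTG at 40.1% against 30.1% (adjusted p = 5.8e-04). TATAAA (3.98% against 11.5%) and the homeodomain site TAATTA (1.28% against 4.55%) were rarer at summits, with adjusted p of 5.5e-07 and 6.9e-04. Both depletions depend on the background. Against shuffled summit windows that keep dinucleotides, TATAAA was more frequent (1.64-fold, adjusted permutation p = 0.028) and TAATTA was near its chance level (1.04-fold). Against shuffles that keep only the bases, both were rarer without passing the threshold (TATAAA 0.693-fold, TAATTA 0.464-fold, adjusted permutation p = 0.0995 and 0.0836). The GATA site WGATAR, of interest because EGL-27 has a GATA-type zinc finger, was at 19% of summits and 21.7% of flanks (exact McNemar test, adjusted p = 0.43). In each replicate's own top nuclear peaks the GATA site was at 21%, 16% and 20.6% of summits and 19.3%, 21.8% and 23.7% of flanks. The other 7 fixed motifs (AP-1, forkhead, E2F, T-box, Sp1/KLF, nuclear receptor and Hox/Pbx sites) did not pass the threshold.

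GAGAGA also led the open search, in which 376 of 2080 6-mers were more frequent at summits and 302 less frequent by the exact McNemar test. The 6-mers behind it included AGAGAC (30.5% against 3.55%) and CGTCTC (27% against 4.12%), while AAAAAT was depleted (14.1% against 49.4%). Of the 376 6-mers more frequent at summits, 3 contained GATA on either strand. The number with GATA among all 2080 was not counted, so this count alone shows no lack of GATA sites. Summit windows had 48.2% GC and flanks 35.7%. The GATA site became significantly rarer at summits with 100 bp windows (0.807-fold, adjusted exact p = 0.011), with the left flank (0.788-fold, adjusted p = 0.0497) and at promoter summits alone (0.663-fold, adjusted p = 0.020). The GATA site went the other way, without passing the threshold, outside promoters (1.15-fold), without replicate 2 (1.05-fold) and against dinucleotide shuffles (1.19-fold, adjusted permutation p = 0.093). Against shuffles that keep only the bases it was 0.950-fold. Its direction thus depends on the background. GAGAGA was 2.00-fold more frequent against dinucleotide shuffles and 5.41-fold against shuffles that keep only the bases. The CACGTG call was lost without replicate 1 (3.00-fold) and without replicate 3 (2.60-fold), the TAATTA call without any of the replicates (0.286-fold to 0.333-fold), and the TATAAA call without replicate 1 (0.467-fold).

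**Figure D4:**
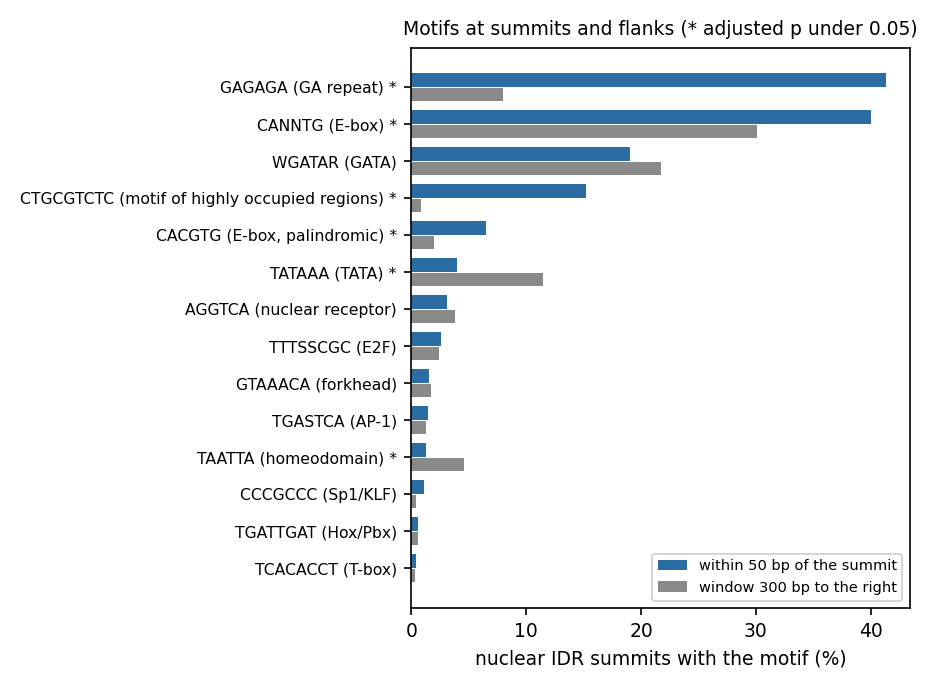
Share of the 704 nuclear IDR summits (x axis, percent) with each of 14 fixed motifs within 50 bp of the summit (blue) and in an equal window 300 bp to the right (grey). GAGAGA was at 41.3% of summits and 7.95% of flanks, while WGATAR was at 19% and 21.7%.

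The transgene gene egl-27 stood in a dense group of peaks, and unc-119, the other gene of the strain's construct, in none. Within 30 kb of egl-27 (chromosome II, 6835008 to 6847908) there were 11 IDR peaks, compared with 0.512 for that length of nuclear genome. The top lists of replicates 1, 2 and 3 had 14, 12 and 16 peaks there. The 11 peaks ran from 6822311 to 6853436, a span of 31.1 kb that also covers neighbouring genes. Within 30 kb of unc-119 (chromosome III, 10902641 to 10908935) there were 0 IDR peaks and 0 peaks of any replicate's top list, compared with 0.465 for that length. With so few peaks expected, a count of 0 among these strongest peaks cannot tell whether the construct affects signal there. Relaxed pooled peaks numbered 14 in the 66295 bp around unc-119 and 51 in the 72901 bp around egl-27, where the nuclear genome held 0.232 per kb. Signal at egl-27 can come from extra copies of the sequence as well as from binding at the native gene, and the lists do not separate these.

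**Figure D5:**
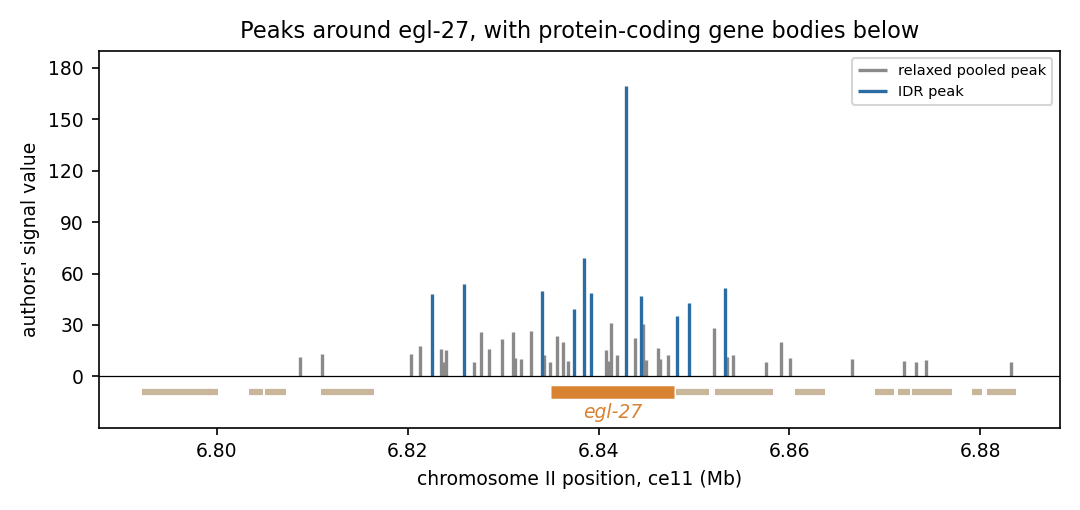
Relaxed pooled peaks (grey) and IDR peaks (blue) around egl-27, drawn at their summits on chromosome II (x axis, Mb, ce11) with the authors' signal value as height, and protein-coding gene bodies below. The 11 IDR peaks lie between 6822311 and 6853436, with the highest at 169.3 inside egl-27.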

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

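The tests of peak density around egl-27 and of the mitochondrial peaks were chosen after the results were seen, and the motif tests were set before their results were seen. No group had the 4 samples that the test for outlying samples needs, and the design has no second group, so no biological explanation by a difference between groups was tested.

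Mitochondrial peaks were flagged for a closer look. They were part of the replicate comparisons, the location classes and the gene lists, and were left out of the shares per chromosome and the motif tests. Replicate 1 had 10 and replicate 2 had 28, while replicate 3 had 0 among 30000 peaks. The length of the lists does not account for this, because the 10 peaks of replicate 1 came from a list of 15286. The peaks of replicate 2 covered 57.1% of the mitochondrial genome, and those of replicate 1 covered 29.9%. Of the 30000 peaks of replicate 2, 29985 had the same width of 410 bp, so coverage mostly restates the number of peaks. It cannot tell a broad signal from single sites. Strain source and fragmentation cannot be told apart as causes, since only 1 replicate carries the labels of replicate 3, and a filter on mitochondrial signal in that replicate alone was not tested and also stays open.

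The group of IDR peaks around egl-27 may come from extra copies of the segment in the transgene, which the peak lists leave open. Relaxed pooled peaks were 5.23 times as dense inside the span of 31.1 kb as in the 30 kb beyond each end. The densities were 1.22 per kb against 0.133 and 0.333, and 0.232 per kb over the nuclear genome. The span was set by the 11 IDR peaks, which are among the 38 relaxed peaks counted, so part of the ratio follows from its choice. Density also does not separate extra copies from binding, so it cannot decide. Whether these summits also carry the motifs of other sites stayed open. GAGAGA or CTGCGTCTC was at 3 of the 11 summits (27.3%) and at 48.8% of the others, and Fisher's exact test gave p = 0.23 with so few summits. Binding at the native gene was not excluded.

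The GA repeat at the summits was set against base composition and masked repeats. Shuffled summit windows that keep only the bases carried GAGAGA in 7.65% of cases on average and 10.7% at most over 200 shuffles. The real windows had 41.3%, a ratio of 5.41, so base composition alone accounts for little of the share. Shuffles that keep every dinucleotide carried it in 20.7% on average and 24.4% at most, a ratio of 2.00. These shuffles keep the GA and AG steps of the repeat itself, so they cannot tell how much of the share comes from dinucleotide composition. Among the 304 summits with no masked base within 50 bp, GAGAGA was at 35.9% of summits and 7.24% of flanks, a ratio of 4.95 (exact McNemar test, p = 1.3e-18), which argues against masked repeats. Accessibility of these sites to many factors was not tested, because peaks of other proteins were not analysed here.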

How the results depend on the processing

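Alternatives named here as added were chosen after the data were seen: leaving out the egl-27 region, shuffled windows, summits free of masked bases, nearest 5′ ends at any distance, a comparison group without piRNA genes, promoter and other summits apart for the X share, nuclear peaks only for recovery and overlap, and all alternatives of the 6-mer search, of the egl-27 count, of chromosomes other than X and of location classes other than promoters. The promoter, chromosome X and autosome centre results and the calls of ribosomal proteins, chemoreceptors, GAGAGA and CTGCGTCTC kept their direction and side of the threshold under every alternative run. The promoter excess ranged from 1.49-fold to 2.37-fold and the X excess from 1.31-fold to 1.76-fold. The number of peaks fell by construction to 352 when the lower-signal peaks were left out, 198 in the top lists of all 3 replicates, and 239 to 305 without each replicate. Mean recovery rose to 75.4% with 2 times as many top peaks. Mean overlap of replicate pairs was 37.0% with 2 times as many top peaks, 33.9% for summits within 100 bp, and 40.2% to 47.9% without each replicate. The number of lists called was 9 with 2000 bp windows, 2 among the 352 peaks of highest signal, and 9, or 7 when matched by upstream distance, with the nearest 5′ end at any distance. The odds ratio of translation factors was 5.03 among the 352 peaks of highest signal and 6.21 to 19.9 without each replicate. That of microRNA genes was 1.38 with 500 bp windows, 1.97 against genes with a relaxed peak and 1.83 against genes other than piRNA genes (added). It was 1.10 with the nearest 5′ end only and 2.46 among the 352 peaks of highest signal. Without each replicate it was 0.971 to 4.25, and the lowest value, which shows no excess, was without replicate 1. In lists matched by upstream distance, the number of microRNA genes was 1.70 times that of the matched lists, short of the threshold. The number of motifs called was 3 to 5 without each replicate. In comparisons with flanks, WGATAR became significantly rarer with 100 bp windows (0.807-fold), the left flank (0.788-fold) and promoter summits (0.663-fold). With dinucleotide shuffles as background it was 1.19-fold, short of the threshold. Against shuffled windows that keep dinucleotides, TAATTA was near its chance level (1.04-fold) and TATAAA reversed to 1.64-fold. The 6-mers called higher numbered 197 among the 352 peaks of highest signal and 100 to 177 without each replicate, where fewer peaks were tested. Peaks near egl-27 numbered 4 to 8 without each replicate. Of 546 other values under alternatives, 499 stayed on their side of the threshold, 20 lost a call, 25 gained a call and 2 changed direction. The 2 were TATAAA, and TAATTA, which came near its chance level. Of the 499, 321 belong to lists with no call to lose. The causes of changed calls were not tested, except where fewer peaks follow from the setting. Read depth is unknown, so its effect could not be set apart.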

Other observations

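Some non-coding genes were bound more often than other annotated genes. With the promoter window used above, 31 of 346 snoRNA genes (8.96%, odds ratio 5.21), 11 of 129 snRNA genes (8.53%, odds ratio 4.85) and 36 of 634 tRNA genes (5.68%, odds ratio 3.19) had an EGL-27 summit, with adjusted p of 4.6e-12, 6.1e-05 and 2.0e-08 by Fisher's exact test over 11 biotypes. Other ncRNA genes (267 of 7764, odds ratio 2.19) and protein-coding genes (444 of 19985, 1.34) were also past the threshold as more often bound. The piRNA genes (0.501%, odds ratio 0.190) and pseudogenes (0.235%, odds ratio 0.116) were bound less often. The 15363 piRNA genes lower the comparison group, and without them the odds ratios were 3.81 for snoRNA, 3.54 for snRNA, 2.32 for tRNA and 1.51 for ncRNA genes, all past the threshold, while protein-coding genes turned to 0.683. Nearby genes share summits, so these counts are not independent, and genes were not matched by expression level.

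EGL-27 peaks also lay in groups. Outside the egl-27 region and the mitochondrial genome, 192 of 693 peaks (27.7%) had another within 10 kb, compared with 13.7% at random placement (permutation p = 0.0010, the smallest that 1000 placements can give). Placement was uniform along each chromosome and did not keep the excess in promoters and autosome centres. Grouping beyond that uneven density was therefore not tested. The largest group had 8 peaks near mdl-1, a Mad-like bHLH gene, on chromosome X at 6736472 to 6750495. Groups of 5 lay near ogt-1 and near zfp-1, and groups of 4 near pqn-41, sma-9 and mxl-3. When every summit was given to its nearest gene at any distance, 6 of 12 heterochronic genes had a peak, namely lin-28, lin-41, lin-42, daf-12, alg-1 and kin-20. Lists matched by upstream distance gave 0.573 on average, so this was 10.5 times the expected number (adjusted permutation p = 0.0019). Insulin signalling and stress genes (7 of 40, 5.44 times) and nuclear hormone receptors (22 of 269, 2.38 times) also passed (adjusted permutation p = 0.0029 for each), while NuRD genes (3 of 14, 5.63 times) passed only unmatched. F-box genes passed as depleted (2 of 315, 0.221 times, adjusted permutation p = 0.040), and C-type lectins (1 of 237, 0.156 times) only unmatched. The match covers upstream distance and not gene length or the number of 5′ ends. This matters because the highest peaks of lin-42, daf-12 and kin-20 lay in introns. The counts at any distance were not repeated without each replicate.

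The tests of biotypes, of grouping, of nearest genes, of CTGCGTCTC at ribosomal protein promoters and of GAGAGA outside CTGCGTCTC were chosen after results were seen, and the 4 tests on the GA repeat below were written down before theirs were computed. GA repeat peaks might be the stronger ones, but the mean log2 signal differed by 0.01 (permutation p = 0.87). The GA repeat might account for the X excess, yet it was at 35.5% of X summits and 43.2% of autosomal ones (odds ratio 0.724, Fisher's exact test, adjusted p = 0.12). It might mark ribosomal protein and translation factor promoters, but there it was rarer, at 14.3% of 28 summits against 38.5% of 343 other promoter summits (odds ratio 0.266, adjusted p = 0.026 by Fisher's exact test). CTGCGTCTC was at 0 of these 28 summits and at 14.6% of the 343 (exact p = 0.021). CTGCGTCTC was at 19.6% of summits with the GA repeat and 12.1% without it (odds ratio 1.77, adjusted p = 0.026 by Fisher's exact test), but the motifs can share bases. With GAGAGA counted only outside CTGCGTCTC the shares were 14.6% and 15.6% (odds ratio 0.926, Fisher's exact test, p = 0.75), so co-occurrence at separate positions was not shown.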
